A study of Mus musculus with 10 samples.

How the data were processed

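RNA was measured by sequencing in keratinocytes isolated from the back skin epidermis of mice, in 10 libraries. Per the labels, the mice were controls or carried a constitutive Gsdma1 knockout together with a floxed Gsdma3 deleted by K14-Cre, a recombinase driven in keratinocytes of the epidermis and hair follicle. Their back skin was rubbed with a mixture of acetone and olive oil (4 parts to 1 part) or with water, 2 times a day for 3 days, and the tissue was collected on day 5. The groups held 3 control libraries under olive oil/acetone, 2 control libraries under water, 3 knockout libraries under olive oil/acetone and 2 knockout libraries under water. Nothing in the labels says that each library came from its own animal, so p-values measure the spread between these libraries, which may be partly technical.

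The deposited values are a normalized read signal per gene, 1 file per library. Per the submitters' processing notes, Trimmomatic 0.38, featureCounts 2.0.0 and DESeq2 1.26.0 were used with the mouse genome build GRCm38 (mm10). The aligner, the annotation release and the strand setting are not given in the sources used here. Within each library every value was a whole multiple of 1 step (100% of values, tolerance 0.1 read), so dividing by the step recovered whole reads. The recovered totals were 15914663 to 21812292 reads per library. PCR reads are not independent molecules, so the intervals and limits computed from reads cover counting error only. Gene identifiers were matched to symbols and coordinates in the GENCODE annotation of GRCm38, where all 17983 identifiers were found.

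The files did not list the same genes. Control libraries listed 16014 genes under olive oil/acetone and 17916 under water, and knockout libraries listed 16557 and 17983. A gene that a file did not list was treated as missing, not as 0. The comparisons used the 15987 genes listed in all 10 files. That requirement was added after the files were seen, because a joint model needs a value in every library. A fit of genes listed in both groups compared was added as an alternative at the same time.

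Each library was divided by a median-of-ratios factor over genes above 0 in all libraries (0.995 to 1.004), and genes with a value of 10 or more in at least 2 libraries were kept, which left 15958 genes. Differences were tested on log2(value + 1) with limma 3.58.1 (lmFit, contrasts.fit and eBayes with a trend, R 4.3.3), with all 10 libraries in 1 model of 4 group means, two-sided. A fold change on this scale understates the change of low genes. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. The contrasts were olive oil/acetone against water in each genotype, knockout against control under each treatment, and the interaction of genotype and treatment. All adjusted p-values below come from limma unless another tool is named.

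The 41 gene lists were fixed before the data were examined, and 40 of them had at least 3 genes tested. They covered the layers and barrier of the epidermis, hair follicle and sebaceous gland, stress, metabolic and inflammatory programmes, and markers of other skin cell types, blood and sex. Lists were tested with camera at an inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a contrast, and again with an estimated correlation and with fry. Counts adjusted over the list alone come from a Benjamini-Hochberg adjustment of the limma p-values within that list. They correct neither for the other genes nor for the choice of lists by their camera p, so they only describe a list. Genes were named by a rule fixed at the same time. It took the target genes in the genotype comparisons, and up to 6 genes with the largest rise and 6 with the largest fall among called genes with a mean of 50 or more in a group and no overlap between libraries, leaving out predicted genes. For the interaction it took up to 4 in each direction, without the overlap condition. It added the 2 members with the lowest adjusted p of each of the 8 lists with the lowest camera p. Genes named outside the rule are said to be so where they appear.

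On simulated counts with 200 changed genes, drawn from the real means, depths and dispersions, limma recovered 88% of changes of 2 on the log2 scale and 32% of changes of 1 for the treatment contrast in controls (15893 genes tested), with 6 false calls among 126. For the genotype contrast under water (15887 genes tested) it recovered 89% and 20%. For the interaction (15904 genes tested) it recovered 70% and 6%. DESeq2 1.42.0 made 39 false calls among 190 in the first of these simulations. In simulated lists, camera called 5 of 5 lists raised by 0.5 on the log2 scale in that contrast (15881 genes tested) and 0 of the other lists. In the genotype contrast under olive oil/acetone (15886 genes tested) it called 5 of 5 and falsely 1 other list. Simulated genes were independent, so this does not show how camera behaves on genes that vary together. Independent genes also give no library that departs in many genes at once. The shares recovered may therefore be too high for these libraries, and need not hold for genes of low level. In the real data Gsdma3 differed between knockout and control by -6.23 under olive oil/acetone and -6.14 under water on the log2 scale. Limma called neither difference (adjusted p = 0.056 and 0.407).

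The alternatives were a pseudocount of 5, no filter on low values, a filter at 50, the values as deposited, equal library totals, a fit of only the 2 groups compared, a robust prior, the replicate number as a block, edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 on the recovered reads, and leaving out each library in turn. Xist was not analysed here.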

Results

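The transcriptome of mouse back skin keratinocytes was profiled in 10 libraries, in control mice and in mice labelled as Gsdma1 knockout with a K14-Cre deletion of Gsdma3, after repeated rubbing with olive oil/acetone or with water. Acetone extracts skin lipids, and the mixture is used to disturb the epidermal barrier. There were 3 libraries per genotype under olive oil/acetone and 2 per genotype under water. The recovered depth ran from 15914663 to 21812292 reads per library, and values are given as normalised read counts. The first principal component held 45.2% of the variance. On it, both knockout water libraries (-57.9 and -53.3) and control water replicate 1 (-71.3) lay apart from the 3 knockout olive oil/acetone libraries (21.7 to 71.1). Control water replicate 2 lay at 4.09, among the control olive oil/acetone libraries (-19.4 to 42.8). On the second component (14.7% of the variance) it lay at 50.6, apart from all other libraries (-43.7 to 27.0).

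The targeted genes were measured first. Gsdma3, a pore-forming gasdermin of the skin (chromosome 11, 98626360 to 98638226, GRCm38), was nearly absent from the knockout libraries. Under olive oil/acetone the control libraries held 103 ± 64.1 normalised counts (SD, n = 3). The knockout libraries together held 1 read against 296 reads in control, a ratio of 0.00319 (95% exact interval 8.04e-05 to 0.0179). Under water the control libraries held 173 ± 156 (SD, n = 2), and the knockout libraries together held 3 reads against 367, a ratio of 0.00882 (95% exact interval 0.00181 to 0.026). The fitted log2 difference was -6.23 under olive oil/acetone (adjusted p = 0.056) and -6.14 under water (adjusted p = 0.407), and neither passed the limma test. DESeq2 called both (adjusted p = 4.95e-06 and 3.03e-05), and edgeR called neither (adjusted p = 0.251 and 0.889). Without either control water library, or without knockout olive oil/acetone replicate 1, limma called Gsdma3 under olive oil/acetone (adjusted p = 0.0127, 0.0142 and 0.0411).

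Gsdma, the gene the labels name Gsdma1 (chromosome 11, 98664351 to 98677708), was not absent in the knockout. Its level was 496 ± 307 (SD, n = 3) in knockout and 602 ± 113 (SD, n = 3) in control under olive oil/acetone (log2 difference -0.44, adjusted p = 0.684). Under water it was 170 ± 0.0594 (SD, n = 2) in knockout and 363 ± 231 (SD, n = 2) in control (log2 difference -0.93, adjusted p = 0.964). A count over the whole gene does not show whether an exon is missing, and these close paralogs may share reads. Gsdma2, between the 2 genes on the chromosome, was listed only in the water libraries, at 0.956 and 9.38 in control and 0 in both knockout libraries.

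**Figure D1:**
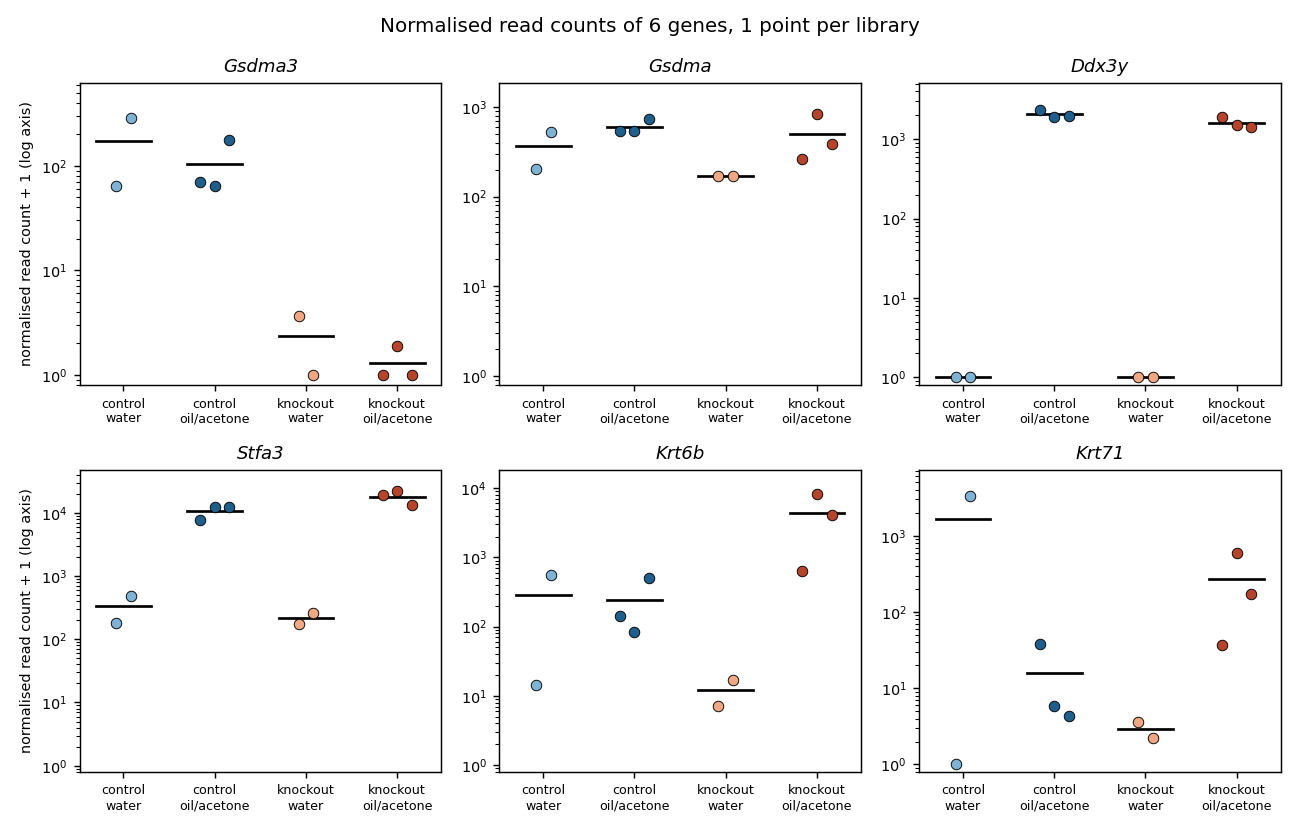
Normalised read count plus 1 (log axis) of 6 genes in each library, with 1 point per library and a line at the mean of each of the 4 groups. Gsdma3 lay at 2.65 or less in all 5 knockout libraries, Ddx3y lay at 0 in all 4 water libraries, and Krt71 reached 3328 in control water replicate 2.

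The comparison of olive oil/acetone with water in control mice asked how intact epidermis responded to the barrier-disturbing mixture. Stfa3, a stefin-type cysteine protease inhibitor, rose from 329 ± 212 (SD, n = 2) to 10789 ± 2733 (SD, n = 3), a log2 change of 5.16 ± 0.39 (SE; adjusted p = 0.000223). Pla2g4e, a cytosolic phospholipase, rose by 2.21 ± 0.26 on the log2 scale (adjusted p = 0.0114), a call lost without control olive oil/acetone replicate 2 or control water replicate 1, and Tgm3, a transglutaminase that crosslinks the cornified envelope, rose by 2.04 ± 0.29 (adjusted p = 0.0474), a call lost in 14 of 21 alternatives. Cxcl14, a chemokine made by resting epidermis, fell by 1.73 ± 0.13 on the log2 scale, from 8054 ± 508 (SD, n = 2) to 2431 ± 170 (SD, n = 3; adjusted p = 0.000227). In all, 10 genes were called by limma, 9 higher and 1 lower, and 2051 genes had an unadjusted p under 0.05. Of the other genes called, Abhd12b was named after its values were seen, and 5 lay on the Y chromosome.

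The Y-linked genes separated the treatments completely. Ddx3y, an RNA helicase gene, measured 2071 ± 237 (SD, n = 3) in control olive oil/acetone libraries and had 0 reads in the control water libraries. Against a limit of 3 reads over the water group it was at least 1458-fold higher. Eif2s3y, Uty and Kdm5d were at least 990-fold, 524-fold and 271-fold higher on the same basis. In the knockout these 4 genes were likewise at 0 reads under water and at least 1047-fold, 815-fold, 377-fold and 272-fold higher under olive oil/acetone. Y-linked transcripts and treatment therefore divided the 10 libraries in the same way, and no library separates an effect of treatment from a difference between libraries with and without Y-linked transcripts.

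Late cornified envelope genes, which build the outermost barrier, had a positive change in 18 of 19 tested members. Of these 0 were called over all genes, and 13 were higher when adjusted over the list alone. Lce1g measured 1035 ± 517 (SD, n = 3) against 80.4 ± 30.8 (SD, n = 2; adjusted p = 0.0736) and Lce6a 444 ± 155 against 61.2 ± 1.77 (adjusted p = 0.0854). Flg, which encodes the barrier protein filaggrin, measured 2869 ± 963 against 288 ± 179 (adjusted p = 0.0822). Genes of epidermal T cells and of Langerhans and dendritic cells had a negative difference in 21 of 22 and 18 of 18 members. Of these 0 were called over all genes, and 13 in each list were lower when adjusted over the list alone. Xcl1, a T cell chemokine, measured 144 ± 52.7 (SD, n = 3) against 628 ± 45 (SD, n = 2; adjusted p = 0.0552), Gzmc, a granzyme, 123 ± 80.8 against 598 ± 441, Fcer1g, an Fc receptor chain, 583 ± 330 against 1403 ± 17, and H2-DMb1, which loads peptide on class II molecules, 181 ± 20.2 against 481 ± 301. Skeletal muscle genes such as Acta1 (64.2 ± 19.4 against 243 ± 157) and Tnnt3 (15.7 ± 4.21 against 76.3 ± 47) had a negative difference in 10 of 10 members, of which 0 were called over all genes and 7 were lower when adjusted over the list alone. Proliferation genes, among them Rrm2 (676 ± 56.6 against 402 ± 10.9) and Cdc20 (1509 ± 278 against 688 ± 253), had a positive difference in 33 of 37 members, with 0 called over all genes and 2 when adjusted over the list alone. Oxidative phosphorylation genes encoded in the nucleus, among them Uqcrc1 (5873 ± 308 against 4479 ± 233), had a positive difference in 74 of 76, with 0 called by either adjustment. Hair shaft and inner root sheath genes, such as the keratin gene Krt71, were high in control water replicate 2 (3328, against 0 in replicate 1). Camera at its preset correlation called 21 of 40 lists. With an estimated correlation it called 1, the sex-linked list (adjusted p = 0.0019), and the lists named here had adjusted p = 0.597 (late cornified envelope, proliferation, T cells, Langerhans and dendritic cells, cornified envelope), 0.609 (oxidative phosphorylation) and 0.359 (skeletal muscle). The count of called genes depended on single libraries. It was 470 (101 higher, 369 lower) without control olive oil/acetone replicate 1, 6 without replicate 2 and 18 without control water replicate 1. DESeq2 called 354, and the fit with the replicate number as a block 58.

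In knockout mice the same comparison called 2143 genes, 1076 higher and 1067 lower. Of the 15958 genes tested by limma, 5580 had an unadjusted p under 0.05, so many members of any list would pass an adjustment over that list alone. Krt6b, a keratin of activated and follicular keratinocytes, rose from 11 ± 6.82 (SD, n = 2) to 4354 ± 3860 (SD, n = 3), a log2 change of 7.99 ± 1.43 (adjusted p = 0.0147). It measured 635, 8341 and 4085 in knockout olive oil/acetone replicates 1, 2 and 3. In control water replicates 1 and 2 it measured 13.5 and 562, so its change in control averages 2 unlike libraries. BC100530, another stefin-family gene, rose by 7.50 ± 0.93 (adjusted p = 0.00569) and Stfa3 by 6.37 ± 0.39 (adjusted p = 2.67e-05), from 216 ± 59.5 to 18026 ± 4382. Stfa1 rose by 4.73 ± 0.63 (adjusted p = 0.0067). Cxcl14, named outside the rule here after its values were seen, fell by 2.02 ± 0.13 (adjusted p = 4.8e-05), from 9788 ± 356 to 2418 ± 177. The largest falls were in Ifi203-ps (-4.55 ± 0.73), an interferon-inducible pseudogene, Pyy (-3.97 ± 0.68), a peptide hormone, Ubxn10 (-3.45 ± 0.70), Tex15 (-3.35 ± 0.78), Cdh4 (-3.19 ± 0.39), a cadherin, and Myo15b (-3.11 ± 0.62), with adjusted p from 0.00543 for Cdh4 to 0.0269 for Tex15.

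Of 37 proliferation genes 29 rose and 0 fell. Rrm2, a ribonucleotide reductase subunit, went from 310 ± 14.2 (SD, n = 2) to 797 ± 27.2 (SD, n = 3; log2 change 1.36, adjusted p = 0.00282), and Cdc20, a mitotic activator, from 428 ± 41.5 to 1625 ± 279 (log2 change 1.91, adjusted p = 0.0067). Of 76 nuclear oxidative phosphorylation genes 40 rose and 0 fell, with Ndufb7 at a log2 change of 1.38 (adjusted p = 0.0147) and Ndufa8 at 0.99 (adjusted p = 0.0156), both subunits of respiratory complex I. Adjusted over the list alone, 31 proliferation and 70 oxidative phosphorylation genes were higher. Interferon-stimulated genes rose in 16 of 32 members (26 adjusted over the list alone), among them the antiviral gene Mx1 (log2 change 3.37, adjusted p = 0.0135). With an estimated correlation camera gave each of these 3 lists an adjusted p = 0.605.

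Barrier genes went in different directions in the knockout. Of 19 late cornified envelope genes 11 rose (14 adjusted over the list alone), including Lce1g (log2 change 3.85, adjusted p = 0.0104) and Lce3d (3.81, adjusted p = 0.0122). Of 24 cornified envelope genes 7 rose and 1 fell (9 and 1 adjusted over the list alone), and Flg, also named outside the rule after its values were seen, rose by 4.15 (adjusted p = 0.00796). Of 20 kallikreins and epidermal protease inhibitors 7 rose (11 higher and 2 lower adjusted over the list alone). Of 13 tight junction genes 9 fell (9 adjusted over the list alone), among them Cgn, the junction protein cingulin (-1.51, adjusted p = 0.016), and Ocln, occludin (-1.17, adjusted p = 0.0198). With an estimated correlation the late cornified envelope, tight junction and protease inhibitor lists had adjusted p = 0.605, and the cornified envelope list 0.739. Markers of blood moved with these genes: all 5 red blood cell genes rose (5 adjusted over the list alone, adjusted p = 0.605 with an estimated correlation), with Alas2, a heme synthesis enzyme, at 3.34 ± 0.36 and Hba-a2, an alpha globin, at 3.87 ± 0.49. The median level of the hair shaft and inner root sheath list stood at 2.96 and 2.13 in knockout olive oil/acetone replicates 2 and 3, on a log2 scale relative to the median library, against -0.11 and -0.16 in the knockout water libraries.

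**Figure D2:**
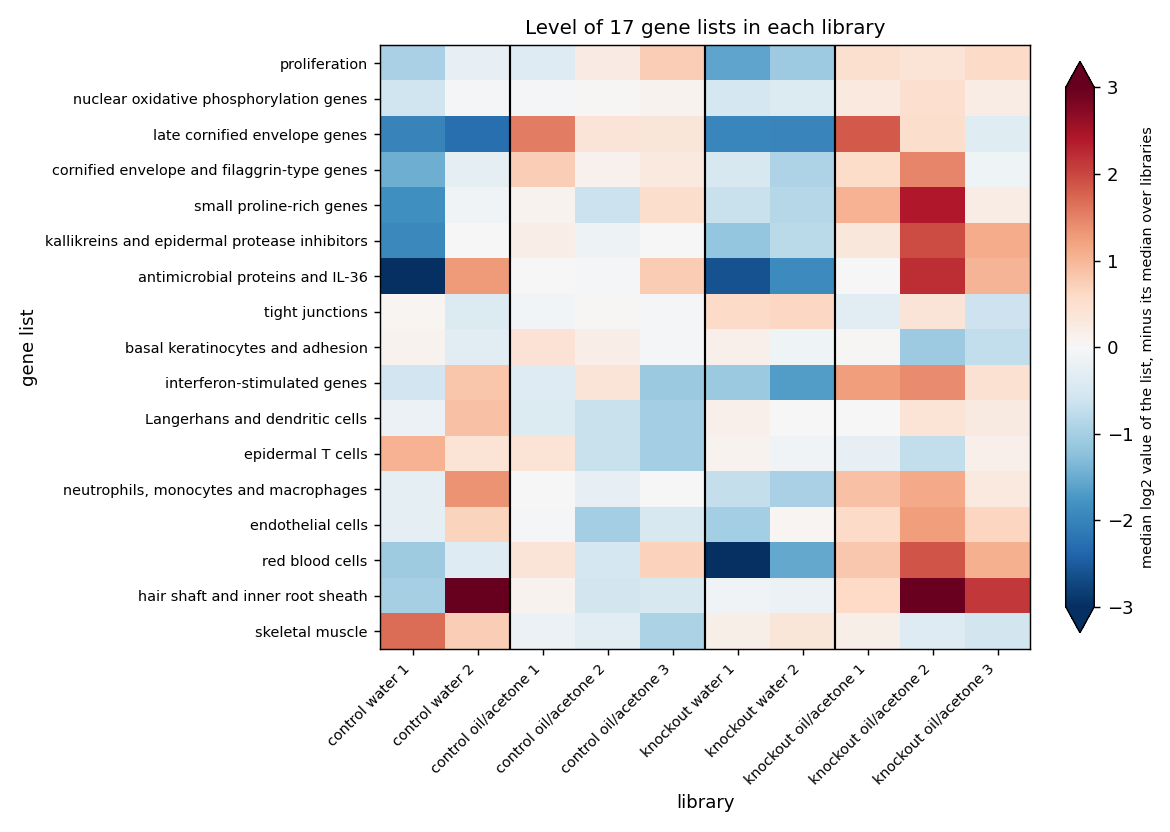
Median log2 value of 17 gene lists (rows) in each of the 10 libraries (columns, ordered by group), minus the median of each list over the libraries; red is higher and blue is lower, with colours capped at 3. Hair shaft and inner root sheath genes stood at 4.37 in control water replicate 2, and red blood cell genes at -3.13 and -1.54 in the knockout water libraries.

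Of the named genes followed here, only the Y-linked ones and Stfa3 kept their call in the knockout with each library left out. The others lost it without knockout water replicate 1. Cxcl14 and Flg, named outside the rule in the knockout, were not followed when libraries were left out. The count in the knockout also rested on single libraries: it was 9 and 34 without knockout water replicates 1 and 2, which leave 1 water library assumed to vary like the other groups, and 424 and 239 without knockout olive oil/acetone replicates 2 and 3. It was 839 without control olive oil/acetone replicate 2, which enters through the shared spread, while a fit of the 2 knockout groups alone called 3872 and DESeq2 called 3626. Scaling the libraries to equal totals changed the split to 1346 higher and 845 lower.

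The comparison of knockout with control under olive oil/acetone asked whether the treated epidermis differed between the genotypes. No gene was called by limma, 1908 genes had an unadjusted p under 0.05, edgeR called 0 and DESeq2 called 168 (97 higher, 71 lower). Interferon-stimulated genes had a positive difference in 32 of 32 members (0 called over all genes, 10 higher adjusted over the list alone). Among them, the RNA sensor genes Ddx58 and Dhx58 measured 444 ± 15.5 against 278 ± 47.4 (SD, n = 3 each; adjusted p = 0.314) and 120 ± 24.6 against 41.5 ± 14.4 (adjusted p = 0.314). Basal keratinocyte and adhesion genes had a negative difference in 18 of 18 (0 called over all genes, 13 lower adjusted over the list alone), with the transcription factor Sox6 at 917 ± 522 against 1913 ± 191 and Lama3, a laminin chain, at 2870 ± 1071 against 4962 ± 384. The median level of this list was 0.03, -1.08 and -0.75 in knockout replicates 1, 2 and 3, and that of the hair shaft and inner root sheath list was 0.59, 2.96 and 2.13. Other lists leaned higher in the knockout with 0 members called over all genes. They were Langerhans and dendritic cells (11 of 18 adjusted over the list alone; Csf1r 893 ± 220 against 340 ± 51.8, Itgax 246 ± 47.9 against 108 ± 8.62), endothelium (5 of 13; Pecam1 204 ± 35 against 58 ± 31.2, Esam 40.3 ± 11.1 against 8.19 ± 2.18), and outer root sheath and bulge (5 of 24 higher and 1 lower; Lhx2 1514 ± 367 against 633 ± 207, Foxc1 1898 ± 189 against 1022 ± 257).

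Further lists under olive oil/acetone had 0 members called over all genes. They were oxidative phosphorylation (76 of 76 positive, 0 called by either adjustment; Ndufb7 712 ± 97.8 against 462 ± 74.3 and Ndufv1 2032 ± 149 against 1496 ± 247), sebocytes (14 of 15 positive, 4 higher adjusted over the list alone; Mgst1 949 ± 219 against 488 ± 107, Soat1 817 ± 445 against 326 ± 108) and small proline-rich genes (12 of 12 positive, 1 higher adjusted over the list alone; Sprr1b 5878 ± 2507 against 2320 ± 486, Sprr2a2 70.1 ± 85.7 against 5.22 ± 4.66). The libraries of the genotypes overlapped in Soat1 and Sprr2a2, and the median sebocyte level was 1.52 in knockout replicate 2 against -0.21 and 0.20 in replicates 1 and 3. Red blood cell genes had a positive difference in 5 of 5 (0 called by either adjustment). Camera at its preset correlation called 17 lists and with an estimated correlation 0, the lowest adjusted p being 0.546. Without knockout olive oil/acetone replicate 1 limma called 51 genes (5 higher, 46 lower). Without either control water library it called 4 genes, Gsdma3, Pi15, Krt6a and Tom1l2, of which the last 3 were named after their values were seen. A fit of the 2 groups alone called Gsdma3 and Pi15.

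Under water the genotypes were compared without the mixture. No gene was called by limma. Of 15958 genes tested 795 had an unadjusted p under 0.05, about the share that this threshold gives where no gene differs. The edgeR test called 0 genes and DESeq2 called 6 genes, all lower in the knockout. These were Gsdma3, Dab2, Spp1, Ptafr, Ifi203 and 5830411N06Rik, of which all but Gsdma3 were named after their values were seen. Interferon-stimulated genes had a negative difference in 30 of 32 members (0 called by either adjustment), with Zbp1, a nucleic acid sensor, at 25.7 ± 17.4 against 78.6 ± 18.7 (SD, n = 2 each; adjusted p = 0.964). Proliferation genes had a negative difference in 34 of 37 (0 called by either adjustment), with Cdk1 at 208 ± 76.4 against 391 ± 120 and Ccnb2 at 140 ± 24.3 against 278 ± 87.6. Suprabasal keratinocyte genes had a positive difference in 19 of 20 (0 called by either adjustment), with Grhl1 at 6432 ± 116 against 4331 ± 190. Further lists had 0 members called over all genes and some lower when adjusted over the list alone: epidermal T cells (1 of 22), neutrophils, monocytes and macrophages (2 of 16), red blood cells (5 of 5) and skeletal muscle (3 of 10). Xcl1 measured 216 ± 6.24 against 628 ± 45, Mrc1, a macrophage receptor, 6.57 ± 0.688 against 33 ± 19.5, Aloxe3, an epidermal lipoxygenase, 1057 ± 54.6 against 555 ± 151, Hba-a2 42.9 ± 22 against 171 ± 92.2, and Myh4, a muscle myosin, 11.1 ± 3.23 against 57.7 ± 36.6. The median level of the hair shaft and inner root sheath list was 4.37 in control water replicate 2, and its genes had a negative difference in 19 of 20 members (0 called by either adjustment). That library also stood above control water replicate 1 in interferon-stimulated genes (0.83 against -0.57) and in neutrophils, monocytes and macrophages (1.35 against -0.30). It stood below it in epidermal T cells (0.40 against 1.03) and skeletal muscle (0.73 against 1.67). Camera called 20 lists at its preset correlation and 0 with an estimated correlation, the lowest adjusted p being 0.483. Without control water replicate 2, limma called 1 gene, Dab2.

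The interaction asked whether the treatment effect differed between genotypes. No gene was called by limma, 1897 had an unadjusted p under 0.05, the lowest adjusted p was 0.163, edgeR called 0 and DESeq2 called 196 (156 higher, 40 lower). The difference between 10 and 2143 called genes is therefore not itself shown by limma. All 10 genes called in control were also called in the knockout, with the same sign, and 5 of them lay on the Y chromosome. Both contrasts hold the same division by Y-linked transcripts, so the shared signs and the correlation of the treatment effects cannot be credited to treatment alone. Of the 2143 genes called in the knockout, 1873 (87.4%) had the same sign in control. Over all genes the median size of the log2 change was 0.47 in the knockout and 0.27 in control. Across genes, which are not independent replicates, the treatment effects of the 2 genotypes, which share no library, correlated at Pearson's r = 0.439 and Spearman's rho = 0.439. The genotype effects under the 2 treatments correlated at r = -0.335 and rho = -0.347.

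**Figure D3:**
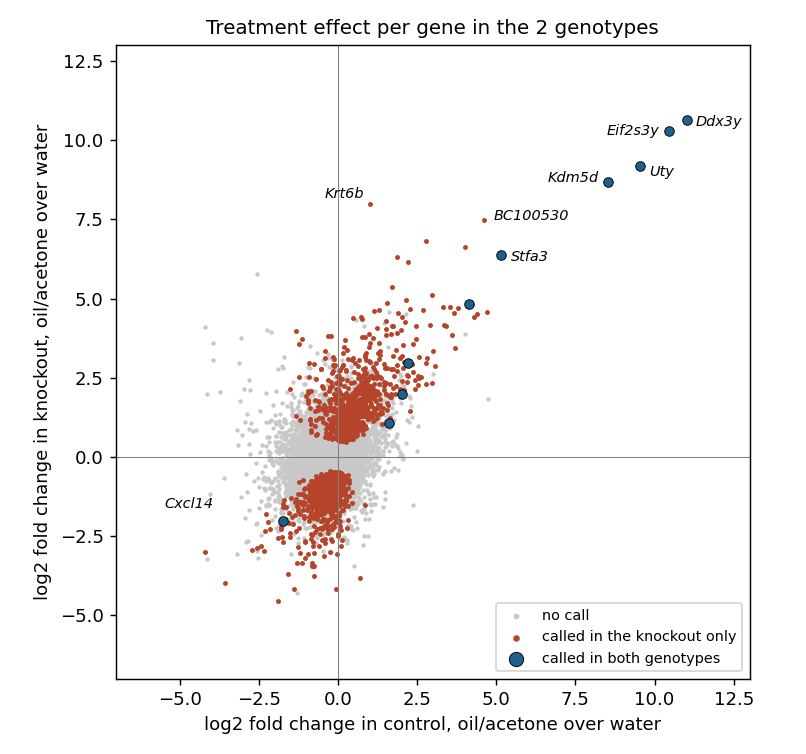
Log2 fold change of olive oil/acetone over water per gene in control (horizontal axis) and in knockout (vertical axis), 1 point per gene for 15958 genes; grey points were not called, red points were called in the knockout and blue points in both genotypes. The 4 named Y-linked genes lie at the upper right, and Krt6b lies at 1.02 in control and 7.99 in the knockout. Krt6b measured 13.5 and 562 in control water replicates 1 and 2.

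All 32 interferon-stimulated genes were positive, meaning a more positive log2 change in the knockout (0 called over all genes, 26 higher adjusted over the list alone). Zbp1 had an interaction of 2.92 ± 0.60 (adjusted p = 0.356) and Oas1a, an antiviral synthetase, 3.53 ± 0.81 (adjusted p = 0.356). Also positive were 35 of 37 proliferation genes (0 called by either adjustment; Mcm2 1.15 ± 0.34), 18 of 18 Langerhans and dendritic cell genes (11 adjusted over the list alone; Ctss 1.97 ± 0.53), 22 of 22 epidermal T cell genes (4 adjusted over the list alone; Xcl1 2.24 ± 0.45, Gzmc 3.37 ± 0.84) and 13 of 13 endothelial genes (6 adjusted over the list alone; Tie1 3.31 ± 0.94). Hair shaft and inner root sheath genes, high in control water replicate 2, were positive in 18 of 20 (0 called over all genes, 1 higher and 1 lower adjusted over the list alone). That library also had higher median levels than control water replicate 1 in other lists. They were 0.83 against -0.57 (interferon-stimulated), 0.87 against -0.17 (Langerhans and dendritic cells), 0.66 against -0.27 (endothelium) and -0.24 against -0.98 (proliferation). Epidermal T cells went the other way, with 0.40 against 1.03. Red blood cell genes were positive in 5 of 5 (0 called over all genes, 5 higher adjusted over the list alone). Basal genes were negative in 17 of 18 (0 called by either adjustment; Itga2 -1.92 ± 0.72, Lamb3 -1.22 ± 0.44). Camera called 20 lists at its preset correlation and 0 with an estimated correlation, the lowest adjusted p being 0.45. Without control water replicate 1 limma called 72 interaction genes (58 higher, 14 lower), and without replicate 2 it called 1, Dab2. The correlation of the treatment effects was 0.0356 without replicate 1 and 0.651 without replicate 2, and that of the genotype effects was 0.0754 without replicate 2.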

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

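Apart from the test with the hair list as a covariate, the tests in this part were chosen after the result they measure was seen. No group held 4 libraries, so single outlying libraries were not tested for.

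The difference between olive oil/acetone and water, with 2143 genes called in the knockout, follows a division of the libraries by Y-linked transcripts. The read totals of 3 of 3 knockout olive oil/acetone libraries lay inside the range of the knockout water libraries. Those water libraries held the highest and the lowest total of all 10 libraries (21812292 and 15914663), so no other library could lie outside their range. The test therefore does not decide on depth, and shows only that read totals did not divide the knockout libraries by treatment. The sex of the animals cannot be told apart from the treatment, because 0 of the 10 libraries broke the match between Y-linked reads and treatment. With the level of the hair shaft and inner root sheath list as a covariate, 298 of the 2143 genes stayed called. Over the 2143 genes the median size of the log2 change went from 1.11 (median SE 0.261) to 0.913 (0.259) and 100% kept their sign, so whether follicle content could account for part of the changes stays open.

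Control water replicate 2 carried hair keratin transcripts: Krt71, Krt25 and Krt27, keratins of the inner root sheath, measured 3328, 1876 and 1306 there, against at most 2.65, 10.9 and 6.17 in the other water libraries. Of 29 listed genes of the hair shaft and inner root sheath list, 25 were highest in this library, as cells of growing hair follicles in that preparation could give. Only 20 of the 29 were listed in all files, so for the rest some libraries had no value to compare. A library of another group under a wrong label is argued against, since Gsdma3 measured 283 there, with 0 Y-linked reads.

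The treatment called 10 genes in control and 2143 in the knockout. A larger response in the knockout stays open, since limma called 0 interaction genes and DESeq2 196. Control water replicate 2 may contribute, because it lay among the control olive oil/acetone libraries on the first principal component (4.09), though apart from all libraries on the second (50.6). Without it the correlation of the treatment effects across genes was 0.651, against 0.0356 to 0.472 without any other single library. Over all genes the median size of the log2 change in control went from 0.27 to 0.41 when it was left out. In the knockout, with all libraries, it was 0.47. Without control water replicate 2 a single control water library is left, and noise alone makes log2 changes against 1 library larger in size. The size without control water replicate 1 was not computed. Neither these sizes nor counts of called genes can therefore show whether the gap between the genotypes closes.

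The 6 olive oil/acetone libraries can be split in only 10 ways, too few for a share under 0.05. The real split called 0 genes, a count that all 10 splits reached, and the highest other split called 20. That split set control replicates 1 and 2 with knockout replicate 1 and had 3574 genes at an unadjusted p under 0.05 against 1908 for the real one, so the 6 libraries differed along that line in more genes than between genotypes. The real split called 17 lists at the preset correlation. Of the 10 splits 5, the real one included, called as many or more, and the highest other called 25.

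In 10 named genes the olive oil/acetone libraries all lay on one side of the water libraries in control and all on the other side in the knockout. These genes had been named from the genotype or interaction contrasts, which favours such a pattern, and its share over all genes was not computed. Over all genes the treatment groups did not overlap in 24.2% in control and 57.9% in the knockout, against 20% by chance. The limma interaction test called none of them, with adjusted p from 0.356 to 0.366. The interaction on the log2 scale was -1.49 for Aloxe3, 1.53 for Csf1r, 1.97 for Ctss, 0.97 for Ddx58, 2.08 for Esam, 3.37 for Gzmc, 1.55 for Itgax, 1.88 for Soat1, 3.31 for Tie1 and 2.92 for Zbp1.

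Sprr2a1, a small proline-rich envelope gene not listed in the control water files and so left out of the comparisons, averaged 61.1 in the knockout olive oil/acetone libraries (10.4, 150 and 22.6), a mean carried by 1 library, and the lowest lay under the highest control olive oil/acetone value of 13.4.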

How the results depend on the processing

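The fit of genes listed in both groups compared was added after the data were seen; the other alternatives were set before. Genes called for the treatment in control numbered 58 with the replicate block and 354 by DESeq2, and those in the knockout 3872 from the 2 groups alone, 3907 from genes listed in both groups and 3626 by DESeq2. For knockout against control, 2 genes were called under olive oil/acetone in each of these smaller fits and 168 by DESeq2, and 6 under water by DESeq2, which called 196 for the interaction. The other 43 of the 53 counts, from all alternatives except leaving out a library, lay within 1.5 times the reported one or were 0 like it. Leaving out 1 library gave 6 to 470 genes for control, 9 to 3141 for knockout, 0 to 51 and 0 to 1 for the genotypes under olive oil/acetone and water, and 0 to 72 for the interaction. Leaving out 1 library, the Gsdma3 difference ranged from -6.53 to -5.75 under olive oil/acetone (adjusted p = 0.0127 to 0.502) and from -7.22 to -5.06 under water (0.0653 to 1); with a pseudocount of 5, edgeR and DESeq2 it was -4.20, -7.86 and -8.23 under olive oil/acetone and -4.49, -6.77 and -6.87 under water. The correlation of treatment effects ranged from 0.0356 to 0.651, and that of genotype effects from -0.498 without control water replicate 1 to 0.0754, a turned sign, without replicate 2. The cause of these shifts was not tested, except that a left-out water library leaves 1 in its group. Under equal totals the median log2 change of all genes was 0.13 in the knockout treatment contrast, 0.11 in the genotype contrast under olive oil/acetone and 0.19 in the interaction, against 0.01, 0.02 and 0.03 as reported, and 61.4% of knockout calls were then higher against 50.2%. None of 96 list directions called by camera turned under the other scalings. Camera with an estimated correlation called 1, 1, 0, 0 and 0 lists in the order control, knockout, olive oil/acetone, water and interaction, and fry called 2, 4, 0, 0 and 0. Whether the replicate numbers pair the libraries stayed unclear: the deviations of 13 same-numbered pairs correlated at -0.105 to 0.45, with 6 over 0.1. With the replicate block 2766 genes were called in the knockout and 0 in each genotype contrast and the interaction. The 95 results of genes named by the rule, and the target genes, kept their direction in all alternatives run; other printed results were not followed across them. Apart from leaving out a library, 1 called result of the rule lost its call, Tgm3 in control, under 6 alternatives (14 with left-out libraries). At 15914663 reads or more per library, 3 reads over 2 water libraries correspond to a value of 1.42 in control and 1.53 in the knockout, which limits the folds of genes at 0.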

Other observations

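The genes of the first 2 paragraphs and the test of X-linked genes were chosen after their values were seen, and the test near the targeted genes before. In the knockout, olive oil/acetone against water, 5 of 19 gasdermin and inflammasome genes rose and 0 fell (9 higher and 2 lower adjusted over the list alone; adjusted p = 0.705 with an estimated correlation). Gsdmc, a gasdermin cleaved by caspases, went from 200 ± 16.2 (SD, n = 2) to 1119 ± 785 (SD, n = 3), a log2 change of 2.23 (adjusted p = 0.0387). Gsdmc2 changed by 2.11, Gsdmd, the gasdermin of classical pyroptosis, by 1.45, and the DNA sensor Aim2 by 1.42. Of 12 antimicrobial and IL-36 genes 4 rose (9 adjusted over the list alone; adjusted p = 0.605 with an estimated correlation), among them the IL-36 cytokine genes Il1f6 (4.74), Il1f8 (4.54) and Il1f9 (2.54). In control Gsdmc measured 296 ± 74 (SD, n = 3) under olive oil/acetone and 172 ± 140 (SD, n = 2) under water (adjusted p = 0.489), and its interaction had adjusted p = 0.543.

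In the same contrast, of 18 basal keratinocyte and adhesion genes 5 fell (11 adjusted over the list alone; adjusted p = 0.663 with an estimated correlation), including Trp63 (-0.99), the master regulator of basal keratinocytes, and Krt15 (-0.91). Of 13 endothelial genes 5 rose (7 adjusted over the list alone; adjusted p = 0.605 with an estimated correlation), including Pecam1 (1.74) and Plvap (2.87). Of 16 genes of neutrophils, monocytes and macrophages 4 rose and 1 fell (5 and 1 adjusted over the list alone; adjusted p = 0.663 with an estimated correlation), including the complement genes C1qa (1.06), C1qb (2.16) and C1qc (2.09).

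A hypothesis for the absence of Y-linked reads under water is that the series holds water libraries from females and olive oil/acetone libraries from males, which would suggest a higher level of X-linked escape genes under water. Of 4 X-linked genes known to escape inactivation, 3 (Kdm6a, Kdm5c and Eif2s3x) were lower in all 6 olive oil/acetone libraries than in all 4 water libraries, with Kdm6a at 1235 ± 225 (SD, n = 6) against 1933 ± 160 (SD, n = 4). Ddx3x overlapped, with a highest olive oil/acetone value of 11881 and a lowest water value of 8671. The separation of Kdm5c was narrow, with a highest olive oil/acetone value of 2925 and a lowest water value of 2983. The share of all genes that separate the libraries in this way was not computed. An effect of treatment on these genes would look the same. The values therefore go with a difference in sex, which the labels do not give, but do not show it.

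Variants carried along with the targeted alleles on chromosome 11 could make nearby genes differ between genotypes, and this was tested on a prediction written before the values were computed. Of 252 genes within 5 megabases of Gsdma3, 13.5% had an unadjusted p under 0.05 under olive oil/acetone against 11.9% of the other genes (one-sided Fisher's exact p = 0.25, adjusted p = 0.501). Under water the shares were 1.59% and 5.04% (one-sided Fisher's exact p = 0.999, adjusted p = 0.999). Neither Fisher test passed. The share near the locus was still higher under olive oil/acetone, whereas the prediction without linked variants required no higher share under both treatments. The test therefore does not decide on linked variants.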
